A study of Homo sapiens with 2 samples.

How the data were processed

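RNA of J82 bladder cancer cells was taken 48 h after transfection with non-targeting siRNAs or ZFP36L1 siRNAs and sequenced on a BGISEQ-500, per the labels' protocols, with 1 library in each group. The deposited table holds raw counts per Ensembl gene, not normalized, for both libraries, and the exonic length of each gene. Reads were aligned with HISAT to hg19 and counted with featureCounts, per the submitters' processing notes. The counting used featureCounts v1.5.0-p3 with Ensembl release 82 annotation of GRCh37 and a minimum mapping quality of 10, with no option for strand, read pairs or multi-mapped reads on the command line, per the file header. The HISAT version and the read length are not given in the sources used here. The mapping quality minimum removes reads that fit several places, so genes with near-identical copies can lose counts or exchange them with their copies. Coordinates are those of the count table (hg19), 1-based.

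The table has 57773 genes. Of these, 52338 (90.6%) matched GENCODE release 29 by Ensembl identifier, which supplied gene symbols, gene types and 3' UTR sequences and no coordinates. Of 16780 genes with a mean count of at least 10, 16327 (97.3%) had a symbol, and 12342 of the 12402 protein-coding genes (99.5%) had an annotated 3' UTR. Identifiers with no match held 0.573% of counts in the non-targeting library and 0.595% in the other and stayed in the library sizes.

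Library totals were 25582404 counts for the non-targeting library and 56856474 for the ZFP36L1 siRNA library. Library sizes were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 (0.974 and 1.03). With 1 library per group there are no residual degrees of freedom, so the edgeR quasi-likelihood test could not be fitted and no p-value was computed. For each gene the ratio of CPM, ZFP36L1 siRNA over non-targeting, was given with an exact conditional binomial 95% interval, which covers counting error only and not variation between cultures or PCR duplicates. A gene was called higher or lower at a ratio of at least 2-fold with an interval that excludes 1 and a mean count of at least 10. The floor was 3 counts per library, 0.117 CPM and 0.0528 CPM.

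Gene lists were fixed before the data were examined. For each list the measured members, those at least 1.5-fold higher or lower with intervals excluding 1, and the median log2 ratio with 0.5 added to scaled counts were computed. The median's percentile among 10000 random lists of the same size, drawn from protein-coding genes in 20 bins of mean expression, was computed with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 in Python 3.11.15. A list stands apart when its median is outside the central 95% of random lists. UHRF1, DCP1A, PECAM1 and several histone genes of the lists had no match by identifier. AU-rich heptamers were counted in the longest annotated 3' UTR, with random lists matched on expression and 3' UTR length in 10 bins each, and genes with no annotated 3' UTR were left out.

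Genes were named by a rule also fixed before the data were examined. It takes ZFP36L1 and its paralogs, HIF1A, CCND1 and E2F1, the 12 higher and the 12 lower genes with a mean count of at least 50 whose interval bound nearest to 1 lies farthest from 1, and up to 4 members per list by the same measure. Pseudogenes, pseudoautosomal genes, genes known only by a clone identifier and genes with at least 20% of their 50-base sequences (sampled 1 in 16) in another gene were left out of the 12 higher and 12 lower. A few further list members named in the report were chosen after their values were seen, to account for the counts of higher or lower members.

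Alternatives were total counts, DESeq2 1.42.0 size factors, expression-dependent centring (lowess in statsmodels 0.14.6, span 0.3), no count filter, a mean count of at least 50, 5 added to scaled counts, 1.5-fold, 3-fold, intervals wholly beyond 2-fold, random lists matched on gene length, other AU-rich motifs and matching on A+T content. Leaving out genes with copies elsewhere and drawing random lists from all gene types were added after the data were seen.

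The steps were tested on simulated counts for the same 16780 genes, drawn from the means and sizes of these 2 libraries with counting error only and 200 genes altered. The 95% intervals held the true ratio for 95.7% of genes. Genes altered 2.5-fold were found at 2-fold in 98.0% of cases when higher and 92.9% when lower, genes altered 4-fold in 100% and 97.9%, and 74 of 16293 unaltered genes were called. Lists of randomly drawn genes were tested in a separate simulation of the protein-coding genes. It had no altered genes but added independent gene-to-gene spread to the counting error. Of 1000 such lists with no shift 5.7% fell outside the limits. Of 50 lists with 0.3 added to their members' log2 ratios 92.0% fell above them.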

Results

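The data are gene-level RNA-seq read counts from J82 cells, an established human bladder cancer line, collected 48 h after siRNA transfection. One group received non-targeting siRNAs and the other siRNAs against ZFP36L1, a zinc-finger protein that binds AU-rich elements in mRNA 3' UTRs and promotes their decay. Each group had 1 library. The non-targeting library held 25582404 counts and the ZFP36L1 siRNA library 56856474, a depth 2.22 times as large. A count of 3, taken as the floor, corresponded to 0.117 CPM (counts scaled to library size) in the non-targeting library and 0.0528 CPM in the other. With 1 library per group no difference below has a replicate check, no p-value is given, and each 95% interval covers counting error only. All ratios are the scaled CPM of the ZFP36L1 siRNA library divided by that of the non-targeting library.

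ZFP36L1 itself, the targeted gene, stood at 569 CPM (14178 counts) in the non-targeting library and 163 CPM (9525 counts) in the ZFP36L1 siRNA library. Its ratio was 0.287 (95% interval 0.279 to 0.294), so 28.7% of its mRNA level remained. The gene (ENSG00000185650) lies on the minus strand of chromosome 14 at 69254377 to 69263190 in hg19. Its paralog ZFP36L2 was higher in the ZFP36L1 siRNA library, at a ratio of 1.26 (1.19 to 1.33), and its paralog ZFP36 was lower, at 0.853 (0.783 to 0.929).

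The study asked about mRNAs that ZFP36L1 may regulate, and HIF1A, CCND1 and E2F1 were named for this purpose before the data were examined. E2F1, a transcription factor of S-phase entry, had a ratio of 1.59 (1.5 to 1.67) and stood at 71.7 and 114 CPM. CCND1, which encodes cyclin D1, had a ratio of 1.38 (1.36 to 1.40), with 21911 and 70800 counts. HIF1A, the oxygen-regulated transcription factor subunit, had a ratio of 1.15 (1.12 to 1.18), with 7714 and 20814 counts. Each of these intervals lay above 1, but between cultures ratios of this size have no measured spread here.

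Genes nearly absent from the non-targeting library led the higher side of the transcriptome-wide comparison. DNAJC22 (ENSG00000178401, chromosome 12, 49740700 to 49751309), which encodes a DnaJ co-chaperone family member, had 1 count in the non-targeting library and 715 in the other, a ratio of 305 with an interval from 54.6 to 12076. SAMD11 (chromosome 1, 860260 to 879955) had 13 and 1112 counts (ratio 36.5, 21.3 to 68.8), and its neighbour LINC02593 (852245 to 856396), a long non-coding RNA, 4 and 218 (23.3, 8.96 to 86.2). LRRC32, a cell-surface anchor of latent TGF-beta, had a ratio of 27.1 (13.0 to 67.8), and RSPO1, a secreted potentiator of Wnt signalling, 16.8 (8.40 to 39.2). Among genes with more counts behind them, the adhesion receptor gene ADGRG1 had 418 and 6189 counts (6.32, 5.73 to 7.0), and CRIP2, a LIM-domain protein gene, 115 and 2170 (8.06, 6.68 to 9.81).

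The other genes of the 12 highest by their lower interval bound were COL9A3, a collagen IX chain (3 and 123 counts, ratio 17.5, 5.85 to 86.1), PHOSPHO1, a phosphatase of bone mineralization (9.89, 6.91 to 14.7), the orphan receptor gene GPRC5C (9.68, 7.25 to 13.2), the kinase gene LMTK3 (7.82, 5.81 to 10.8) and BMF, a pro-apoptotic BH3-only gene (7.53, 4.99 to 11.9).

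On the lower side, GABBR2, a GABA-B receptor subunit, had a ratio of 0.171 (0.139 to 0.209), and BCL2A1, an anti-apoptotic BCL2 relative, 0.186 (0.135 to 0.253). TGM2, which encodes transglutaminase 2, was the most abundant of the 12 lower genes apart from ZFP36L1, at 381 and 106 CPM (0.277, 0.269 to 0.286). The remaining lower genes were SIRPB2 (0.223), LAMP3 (0.275), NCKAP5 (0.288), ACP7 (0.295), AOX1 (0.301), MYPN (0.341), NTN4 (0.352) and FABP5 (0.354). FABP5, a fatty acid binding protein gene, shared 16.4% of its 50-base sequences with other genes, so part of its reads could belong elsewhere.

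Of 16780 genes with a mean count of at least 10, 450 (2.68%) were at least 2-fold higher in the ZFP36L1 siRNA library with an interval above 1, and 330 (1.97%) at least 2-fold lower. The minimum is on raw counts, so the deeper ZFP36L1 siRNA library weighs more in it. Weakly expressed genes higher in that library therefore pass more easily than those lower in it, which tilts the 2 counts. Protein-coding genes made up 290 of the higher and 181 of the lower genes. Most genes, 82.3%, lay within 1.5-fold. Pseudogenes and genes with near-identical copies elsewhere supplied 82 of the higher and 112 of the lower genes, and without them the lower count was 218. Because the counting did not use strand, genes overlapping an antisense gene cannot be separated from it.

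**Figure D1:**
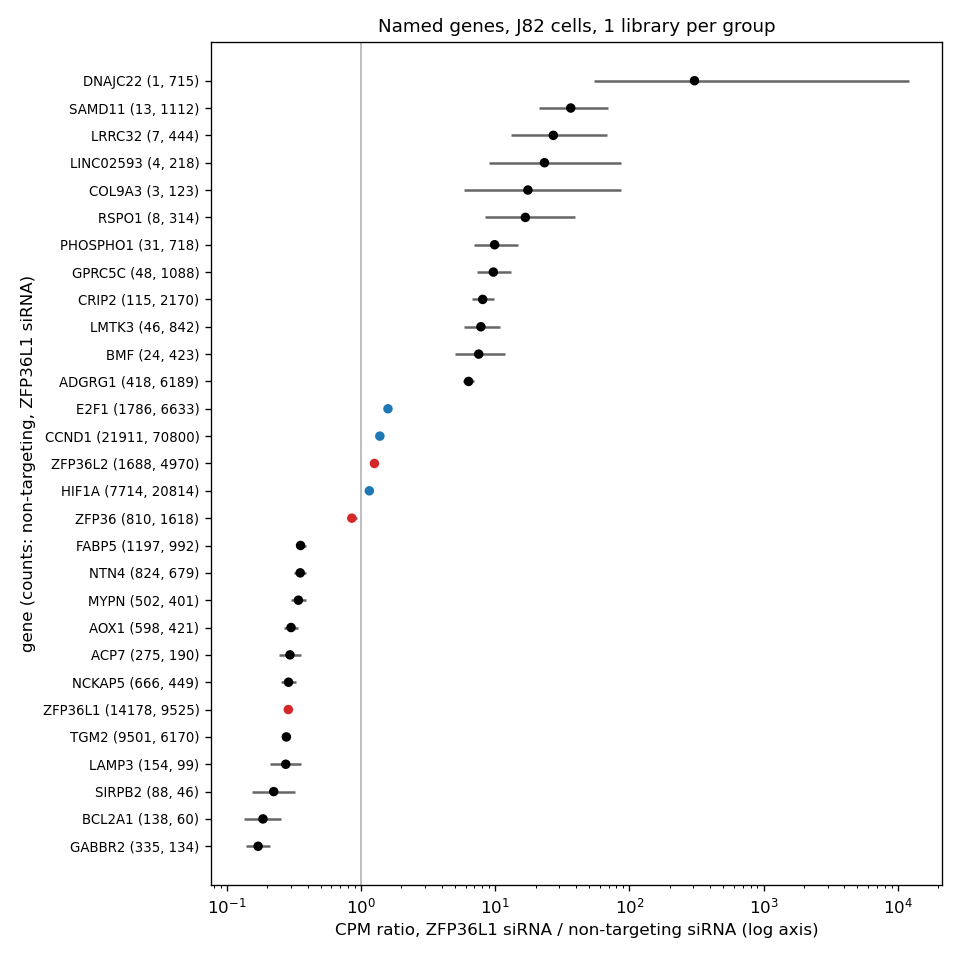
CPM ratio of the ZFP36L1 siRNA library to the non-targeting library on a log axis, for ZFP36L1 and its paralogs (red), HIF1A, CCND1 and E2F1 (blue) and the 12 higher and 12 lower genes (black; ZFP36L1 is also among the lower 12). Points are ratios from 1 library per group, lines are 95% counting intervals and the numbers beside each gene are its counts, and ZFP36L1 sits at 0.287 while DNAJC22, with 1 count in the non-targeting library, has the widest interval.

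Genes of mitosis and DNA replication were lower in the ZFP36L1 siRNA library. All 29 measured G2/M and mitosis genes had log2 ratios below 0, with a median of -0.35, and 3 of them were at least 1.5-fold lower: MKI67, the Ki-67 proliferation antigen (0.60, 0.591 to 0.609), CENPA, the centromeric histone variant (0.628, 0.580 to 0.681), and KIF20A, a mitotic kinesin (0.645, 0.620 to 0.671). The mitotic kinase gene PLK1 had a ratio of 0.687 (0.669 to 0.706). DNA replication and E2F target genes were lower as well, 27 of 33 below 0 with a median of -0.19. CHAF1B, a chromatin assembly factor subunit and the 1 member at least 1.5-fold lower, was at 0.647 (0.616 to 0.679). The DNA replication genes MCM3 and MCM10 were at 0.689 and 0.684. Each list was set against 10000 random lists of protein-coding genes matched on expression, and a list is said to stand apart when its median falls outside their central 95%. The G2/M median fell at percentile 0.0 and the replication median at 0.315.

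The list of G1/S cyclins, CDKs, CDK inhibitors and E2F factors did not stand apart (25 measured, median -0.07, percentile 18.3), its median and mean (0.08) differing in sign, and its median became 0.01 when libraries were scaled by total counts. Within it 4 genes were at least 1.5-fold higher: E2F1 and 3 genes for INK4 inhibitors of CDK4 and CDK6, CDKN2B (2.17, 1.78 to 2.67), CDKN2D (2.13, 1.76 to 2.58) and CDKN2C (1.61, 1.52 to 1.71). E2F4 was lower at 0.657.

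Replication-dependent histone genes stood apart on the higher side, though only 9 of the 19 listed genes were measured. All 9 measured members had log2 ratios above 0, with a median of 1.08 (percentile 100), and 7 were at least 1.5-fold higher. HIST1H2AC had 133 and 1214 counts (3.90, 3.26 to 4.70), which is 5.34 and 20.8 CPM. HIST1H2BD had 58 and 499 counts (3.67, 2.80 to 4.91) and HIST2H2BE 78 and 586 (3.21, 2.53 to 4.12). HIST1H2BC had only 8 and 96 counts (5.12, 2.5 to 12.2). The annotated models of some members are long, such as HIST1H2AC (chromosome 6, 26124373 to 26139344) and HIST1H2BD (26158349 to 26171577). Counts per gene do not show which transcripts of these genes differed, so a change in replication-dependent histone mRNA output cannot be read from them.

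Interferon-stimulated genes were higher in the ZFP36L1 siRNA library. Of 24 measured members 6 were at least 1.5-fold higher and 0 lower, with a median log2 ratio of 0.39 at percentile 99.99. IFIT2 had a ratio of 2.40 (1.74 to 3.35), IFIT3 1.85 (1.48 to 2.34) and IFIT1 1.73 (1.30 to 2.33), all 3 encoding antiviral proteins, and OAS2 2.46 (1.32 to 4.98). These genes stayed low in both libraries, with IFIT3 at 3.89 and 7.21 CPM. RSAD2, OASL, MX2 and IFNB1 were under the count minimum.

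TGF-beta/SMAD target genes also stood apart on the higher side (14 measured, median 0.27, percentile 99.9), with 6 members higher and 2 lower. The inhibitors of differentiation ID2 and ID1 had ratios of 3.83 (3.35 to 4.39) and 2.32 (2.25 to 2.40), and PMEPA1, a feedback regulator of the pathway, 2.05 (1.94 to 2.16). SMAD7, SKIL and ID3 were the other higher members, while the ligand gene TGFB2 was lower at 0.433 (0.385 to 0.486) and the matrix gene TGFBI at 0.533. The list was at percentile 95.5 when genes under the count minimum entered.

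YAP/TEAD target genes (19 measured, median -0.22, percentile 1.78) stood apart on the lower side. TGFB2, which is also in this list, was the 1 member at least 1.5-fold lower, NUAK2 was at 0.743, and LATS2 (1.33) and MYOF (1.30) were above 1. Mesenchymal and matrix genes (21 measured, median -0.24, percentile 0.45) had 3 lower members, the collagenase MMP1 (0.567, 0.504 to 0.637), COL4A1 (0.632, 0.601 to 0.664) and MMP3, and 2 higher, COL5A2 (3.10, 2.25 to 4.35) and ZEB2 (1.63, 1.49 to 1.78). The matrix list lost its position at a mean count of at least 50, where its percentile was 46.4.

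All 13 mitochondrially encoded mRNAs were below 0 (median -0.51, percentile 0.015), and 4 were at least 1.5-fold lower. MT-ND5 had a ratio of 0.612 (0.608 to 0.616), MT-CYB 0.625 and MT-ND4 0.666, and mitochondrial genes took 5.28% of counts in the non-targeting library and 4.11% in the other. MT-ATP6, at 0.657, shared 48.8% of its 50-base sequences with other genes. Ribosomal protein genes were slightly lower (74 measured, 51 below 0, median -0.19, percentile 2.07), with 5 members at least 1.5-fold lower and 2 higher. RPS6 was at 0.547 (0.538 to 0.557) and RPL6 at 0.570 (0.559 to 0.582), while RPS21 and RPS29 were over 1.5-fold higher. That list no longer stood apart when random lists were matched on gene length too (percentile 10.1) or after expression-dependent centring (8.64).

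Cholesterol synthesis genes and SREBP2 targets (20 measured, median 0.12, percentile 98.2) stood apart narrowly, with 0 members beyond 1.5-fold. MSMO1 (1.30, 1.22 to 1.37) and LSS (1.26, 1.21 to 1.31), both enzymes of sterol synthesis, led the list, whose percentile was 95.8 after expression-dependent centring.

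HIF target genes did not stand apart (28 measured, median 0.08, percentile 81.7). LOX (0.519, 0.466 to 0.578) and HK2 (0.549, 0.517 to 0.582) were lower, and the histone demethylase gene KDM4B was higher at 1.74 (1.58 to 1.92). HIF subunits and oxygen-sensing genes (9 measured, percentile 73.2) and glycolysis genes (19 measured, percentile 87.7) did not stand apart either, the glycolysis median (0.01) and mean (-0.03) differing in sign.

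Known ZFP36-family target mRNAs as a list did not stand apart from other genes (36 measured, median -0.12, percentile 7.38). E2F1 was its 1 member at least 1.5-fold higher, and IL1B (0.471, 0.355 to 0.625) and NOTCH1 (0.583) were lower. NF-kB and inflammatory cytokine genes (21 measured, median -0.17, percentile 3.57) held ICAM1, higher at 1.52 (1.42 to 1.62), and IL1B. Immediate early genes went both ways (24 measured, percentile 66.2), with DUSP6 (1.79, 1.69 to 1.91) and JUND (1.60) among 4 higher and DUSP5 (0.566, 0.521 to 0.616) and FOSL1 (0.607) among 3 lower.

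Among genes for mRNA decay and small-RNA factors, CNOT11, a subunit of the CCR4-NOT deadenylase, was lower at 0.543 (0.513 to 0.576), and AGO4, an Argonaute gene, was higher at 1.96 (1.78 to 2.16). The deadenylation and decapping list (25 measured, percentile 44.9), the other AU-rich and stem-loop binding proteins (11, percentile 71.0; RC3H2 at 1.54) and the Argonaute list (13, percentile 65.3) did not stand apart.

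p53 target genes (21 measured, median 0.16, percentile 94.7) had 4 higher members, led by TP53INP1 (2.80, 2.19 to 3.61) and TP53I3 (1.99, 1.82 to 2.19), and 3 lower, including GADD45A (0.521, 0.470 to 0.577) and BTG2 (0.449). Of the BCL2-family and apoptosis regulators (17 measured, percentile 88.8) BMF, BBC3 and BAD were higher and BCL2A1 lower. Unfolded protein and integrated stress response genes (24 measured, percentile 8.23) had 1 lower member, SHMT2 (0.666).

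Luminal urothelial markers (10 measured, percentile 87.1) included FGFR3, which had 16 and 142 counts (3.79, 2.25 to 6.81), and the keratin gene KRT18, lower at 0.625 (0.586 to 0.666). Epithelial junction genes (12 measured, percentile 13.5) included JUP, plakoglobin, higher at 1.96 (1.91 to 2.02). Basal markers had 3 measured members (percentile 65.8), of which CD44 (1.0, 0.989 to 1.01) and EGFR (0.987, 0.965 to 1.01) did not differ beyond counting error. Leukocyte markers (5 measured, percentile 2.57) and endothelial markers (2 measured, percentile 62.1) were mostly under the count minimum, and ESAM (0.592) and LAPTM5 (0.427) were lower. Reference genes (14 measured, percentile 68.5) had 0 members beyond 1.5-fold.

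In all, 10 of 29 lists stood apart, 4 above and 6 below, where 1.45 would by chance. These percentiles describe 2 libraries and treat genes as independent, which genes of one pathway are not.

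**Figure D2:**
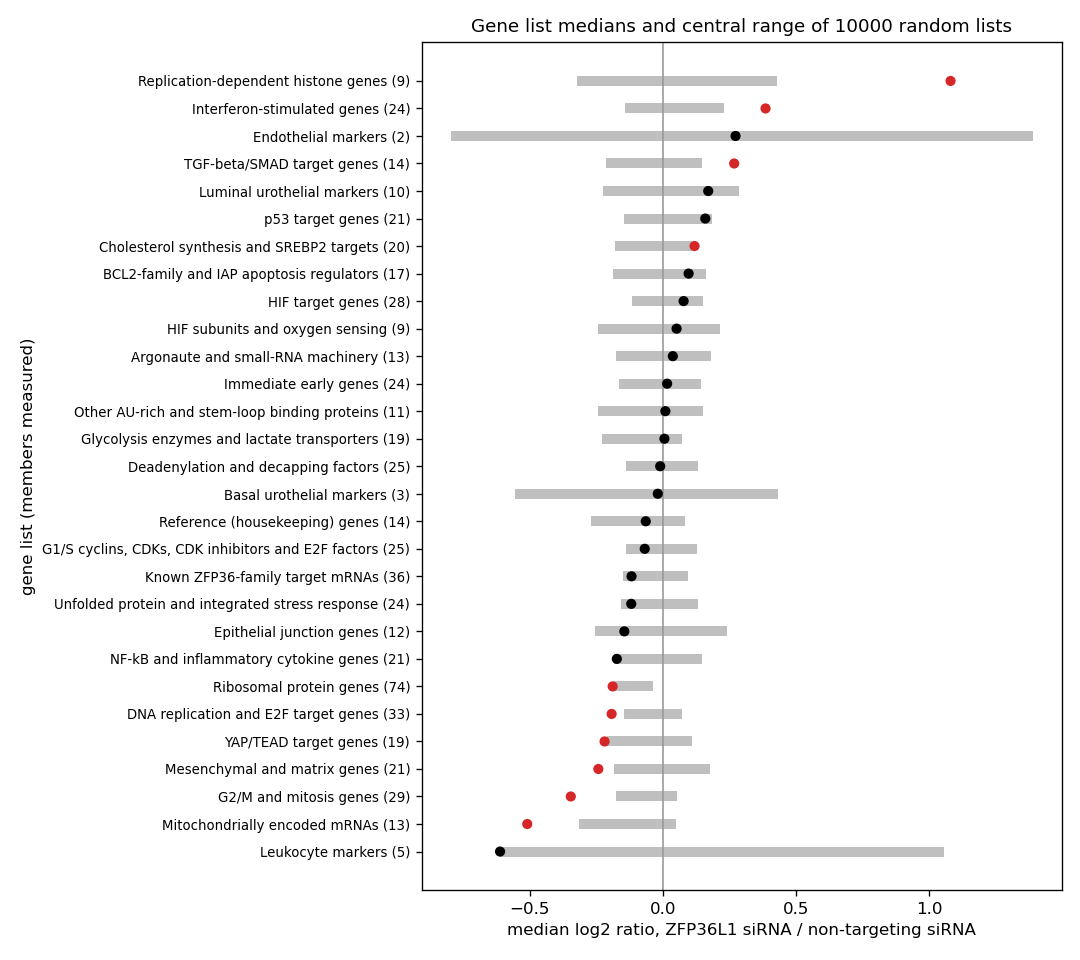
Median log2 ratio of each gene list (points, ZFP36L1 siRNA over non-targeting siRNA, number of members measured in parentheses) over the central 95% of 10000 random lists matched on expression (grey bars). Red points are the 10 lists outside their bar, from histone genes at 1.08 to mitochondrially encoded mRNAs at -0.51.

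Genes were then grouped by the number of AU-rich TATTTAT heptamers in their longest annotated 3' UTR, the kind of element that ZFP36 proteins bind. The 884 genes with 3 or more heptamers had a median log2 ratio of 0.11, and 65.6% of them were above 0. The 1012 genes with 2 heptamers had a median of 0.07 (58.6% above 0), the 2500 genes with 1 had 0.02 (52.8%), and the 7946 genes with 0 had -0.02 (48.2%). Against random lists matched on expression and 3' UTR length, genes with 3 or more heptamers were at percentile 100 (random median 0.03, central 95% from 0.01 to 0.06), those with 2 at 99.99 and those with 1 at 90.9. Genes with 0 heptamers were at percentile 0.0, although their median was 0.06 with total-count scaling, which lifts all genes alike. The shift per gene was small. With the shorter ATTTA pentamer it held in part: the 5810 genes with 3 or more were at percentile 99.97, while those with 0, 1 and 2 were at 93.2, 1.33 and 0.0. With the longer TTATTTATT nonamer, the few genes with 3 or more copies lay within the central 95% of random lists. Those with 1 nonamer lay above it.

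**Figure D3:**
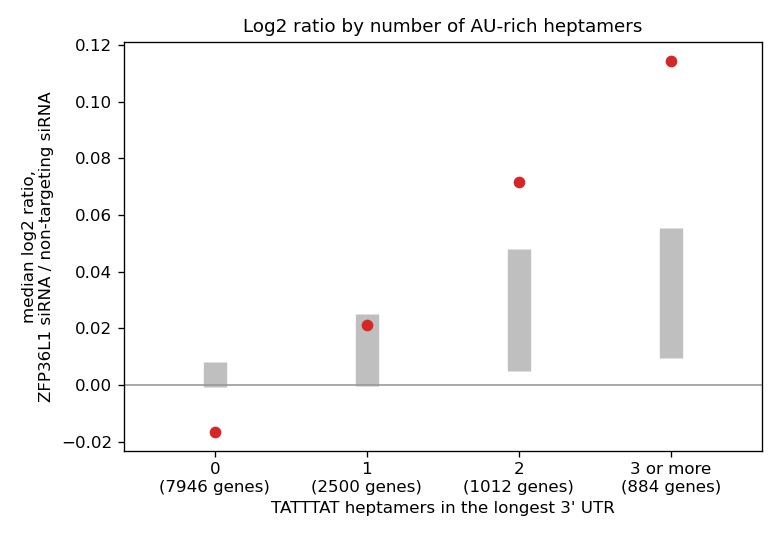
Median log2 ratio (ZFP36L1 siRNA over non-targeting siRNA) by number of TATTTAT heptamers in the longest 3' UTR (red points) over the central 95% of random lists matched on expression and 3' UTR length (grey bars). The median goes from -0.02 at 0 heptamers to 0.11 at 3 or more. Total-count scaling lifts all 4 groups alike by about 0.075, so the first becomes 0.06 and the gradient stays.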

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

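Leaving out genes with copies elsewhere and random lists from all gene types were chosen after the data were seen. No paired analysis was possible because each group had 1 library, and no library could be left out or regrouped for the same reason. The ZFP36L1 ratio was 0.302 with total counts and 0.309 with expression-dependent centring, both outside its counting interval. Counts of higher and lower genes were 215 and 140 at a mean count of at least 50, 1064 and 930 at 1.5-fold, 191 and 81 at 3-fold, and 122 and 85 for intervals wholly beyond 2-fold, all of which follow from the altered threshold. Without pseudogenes and genes with copies elsewhere 218 genes were lower. With total counts 557 genes were higher and 266 lower. Of 261 list percentiles under alternatives 253 kept their side of the limits, and 6 of the 10 lists that stood apart did so under all 9 settings. Percentiles after expression-dependent centring were 95.8 for cholesterol synthesis, 8.64 for ribosomal protein genes and 1.74 for leukocyte markers. Ribosomal protein genes were at 10.1 with gene length matched, TGF-beta/SMAD targets at 95.5 with no filter, and mesenchymal and matrix genes at 46.4 at a mean count of at least 50. Leukocyte markers were at 1.36 against all gene types and 2.38 without genes with copies elsewhere, over 5 measured members. Of 40 percentiles for AU-rich elements 35 kept their side. With the TTATTTATT nonamer, genes with 1 copy were at 99.99 and the 94 genes with 3 or more at 86.8. With the ATTTA pentamer, genes with 3 or more copies stayed above the limits at 99.97, genes with 1 and 2 fell below them at 1.33 and 0.0, and genes with 0 were within them at 93.2. Of 508 log2 ratios of 127 named genes under alternatives, 1 changed sign, that of CLDN1, which was 0.0071 after expression-dependent centring. Except for the thresholds, the cause of these shifts was not tested. The shallower non-targeting library, where 3 counts are 0.117 CPM, limits the ratios of weakly expressed genes.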

Other observations

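The gene families and genes described here were chosen after the data were seen, as were the tests of A+T content, of leukocyte and endothelial markers and of other BMP target genes, and the weighing of the hexamer ranks against the known target mRNAs. Among 389 gene families defined by symbol and at least 5 measured members, 50 had medians outside the central 95% of random lists, where 19.5 would by chance. Pregnancy-specific glycoprotein genes were lower in the ZFP36L1 siRNA library, with all 5 measured members beyond 1.5-fold and a median log2 ratio of -1.73, though members shared a median of 16.8% of their sequence with other genes. The NOP family, largely nucleolar proteins of ribosome assembly, had a median of -0.43 over 8 members, with 0 of them beyond 1.5-fold. Keratin genes had a median of -0.41 over 7 members, with KRT15 and KRT18 at least 1.5-fold lower and KRT7 close to 0 (log2 ratio 0.02). The 437 measured ZNF genes had a median of 0.13 (percentile 100), with 22 at least 1.5-fold higher and 2 lower. ADAMTS proteases had a median of 0.73 over 10 members, with 5 higher, including ADAMTS5, and 2 lower. Protocadherin beta genes had a median of 1.39 over 8 members, with 4 higher, but shared a median of 22.7% of their sequence. TNFSF10, the death ligand TRAIL, had 2 and 47 counts (ratio 10.03, 2.63 to 85.3). These family medians kept their sign under total counts, DESeq2 size factors and expression-dependent centring.

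Pseudogenes held some of the widest differences. Of 2068 tested pseudogenes, 11 had intervals wholly beyond 4-fold higher and 5 wholly beyond 4-fold lower. They shared a median of 38.7% of their 50-base sequences with other genes, against 12.9% in expression-matched random lists of pseudogenes (percentile 99.5). RPL26P35 had 1 and 647 counts with 0.0% shared, PTMAP2 had 508 and 42 with 47.4% shared, and NPM1P6 had 20 and 958. On chromosome 1, 4 copies of mitochondrial genes (MTND1P23, MTND2P28, MTCO2P12 and MTATP6P1) together had 581 and 26357 counts. That sum was 0.0470% and 1.30% of the counts on mitochondrially encoded mRNAs.

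Higher ratios in genes with more AU-rich heptamers may reflect loss of ZFP36L1-dependent decay. Under that hypothesis pieces of the element should lead a ranking of all 4096 hexamers in 3' UTRs, adjusted for UTR length, A+T content and expression. ATTTAT ranked 1 and TATTTA ranked 2 of 4096 toward higher ratios. Both are pieces of the heptamer scored on the same genes, so the ranks do not separate loss of ZFP36L1-dependent decay from other effects on AU-rich mRNAs. Known ZFP36-family target mRNAs leaned the other way, with 15 above and 21 below 0, a median of -0.12 and a percentile of 7.38, within the limits, so the hypothesis stays open. The A+T content of the whole 3' UTR is argued against as the sole cause, since genes with 3 or more heptamers stayed at percentile 100 with A+T content matched. A part played by other A+T-rich motifs stays open. TATTTAT ranked 1 of 21 arrangements of 5 T and 2 A, with an excess of 0.06 in median log2 ratio. TTATTTA, which overlaps it, followed at 0.05, and TTATTAT and TTATATT had 0.047 and 0.045. All arrangements down to rank 20 (ATTTTTA, percentile 99.4) lay above the limits, and only TTTTTAA (89.1) lay within them.

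The second pattern, with pseudogenes and genes that have copies elsewhere left out, is 8 genes under 1 CPM in the non-targeting library with intervals wholly above 4-fold: DNAJC22, SAMD11, LRRC32, LINC02593, COL9A3, RSPO1, BMF and ATOH8. A depth difference was not tested separately, because choosing genes by intervals scaled to library size fixes the outcome of such a test. Leukocytes or endothelial cells in 1 of the cultures stay open: 0 of 26 markers with a row in the table were at least 4-fold higher with an interval above 1, but only 7 of them reached a mean count of 10. Of these, LAPTM5, CORO1A, LCP1, CD79A and ESAM had ratios under 1, and CD14 and CLDN5 had ratios above 1 with intervals that include 1. Other cell types, a difference between the cultures and an effect of ZFP36L1 loss stay open, because 1 library per group may hold any of them.

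Off-target silencing through an siRNA seed could contribute to the genes lower in the ZFP36L1 siRNA library. The siRNA sequences are not given in the sources used here, so all hexamers were scanned for lower ratios. The lowest z, -6.21, belonged to CCGCAG, between the limits of -5 and -8 set before the scan, and the next were the C-rich CCCCGC and AGCCCC. A seed effect cannot be told apart from a sequence composition trend on this evidence.

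ID2, ID4 (ratio 3.60, 3.33 to 3.89) and SMAD6 (4.33, 3.79 to 4.97), all BMP-responsive genes, were higher, which may be part of a wider response of BMP target genes. Of 12 other BMP target genes 6 were measured, and their median was at percentile 65.0. HEY1 (3.18, 1.58 to 7.25) and DLX1 (1.76, 1.62 to 1.91) were higher and NOG (0.504, 0.427 to 0.596) lower, while MSX1 (0.866, 0.720 to 1.04), RUNX2 (1.03, 0.908 to 1.16) and SMURF1 (1.12, 1.07 to 1.18) stayed close to 1. With members going both ways, this leaves a wider response undecided.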
